A study of Drosophila melanogaster with 24 samples.

How the data were processed

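Chromatin was immunoprecipitated with an antibody against the V5 tag from heads or bodies of Drosophila melanogaster and sequenced (ChIP-seq). Per the labels, the flies carried V5-tagged CLK or V5-tagged CYC, or no tag at all (w-, the mock pull-down). They were 5 to 10 days old, kept at 25 °C in 12 h light and 12 h dark, and collected at ZT13, 1 h after lights-off. Per the labels' protocols, chromatin was fixed in 1% formaldehyde for 10 min and sonicated for 6 rounds in heads and 4 rounds in bodies, so the number of rounds follows the tissue. The series holds 24 libraries, of which 12 are pull-downs with a peak list and 12 are inputs without a list of their own. Each of the 6 groups (head or body, CLK, CYC or mock) has 2 pull-down libraries, which the study's design text calls independent biological replicates.

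Reads were mapped with Bowtie 0.12.7 to the dm3 build, per the submitters' processing notes. The names of the deposited lists pair each pull-down with the input of the same tissue, strain and replicate number, and replicates were not pooled. The peak caller and its settings are not given in the sources used here. Each deposited list gives the chromosome, start, end and midpoint of every peak and 2 values per peak without a column name. Both values are treated here as a score in the unit the authors deposited, with no known scale. In all 12 lists every peak had both scores at 2 or above, and all peaks of a list had the same width. The lists hold no read counts, so the depth of each library is unknown. The number of peaks depends on depth and on the calling threshold, and it is the only quantity per library that was tested.

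Peaks were ranked within each list by the first score. The ranking score was left open at the planning stage, and the first was taken after it was seen to be highest at the same positions in the tagged lists. Alternatives that rank by the second score are given with the other alternatives. Peaks above the median score are those at 3.92 or more, the median of the first score over the peaks of all 12 lists. For the second score this median is 4.36. The first-score medians of single lists ran from 2.99 to 8.44, so this cut keeps unlike parts of the lists. It was applied to tagged and mock lists alike. A pair of peaks was counted as overlapping when they shared 1 bp or more. A reproducible peak is a replicate 1 peak that overlaps a replicate 2 peak of the same group. For comparisons between CLK and CYC, reproducible peaks that overlapped a peak of either mock list of the same tissue were removed. For comparisons between tissues, peaks of the 8 tagged lists were merged into regions where they overlapped. A head or body region had a peak in all 4 tagged libraries of the tissue and no peak of a mock list of that tissue. A head-only or body-only region had a peak in all 4 tagged libraries of its tissue, in none of the 4 of the other tissue, and in no mock list. Regions were placed in a cluster when the gap between neighbours was at most 5000 bp.

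Peak numbers per library were compared on the scale log2(peaks + 1) by exact two-sided permutation tests. Labels were permuted within tissue for tagged against mock and for CLK against CYC, and within factor for head against body. The difference between tissues in the tagged-minus-mock contrast was tested by permuting, within tissue, the tagged and mock labels of the residuals of a model with tissue and tag as additive terms. This test is approximate, not exact. The 3 tests of peak number were not adjusted for one another. Overlaps were compared with 1000 placements in which one set was shifted by a random common distance on each chromosome arm. Shares are given with Clopper-Pearson 95% intervals. These intervals cover counting error only, and peaks are not replicates, so no p-value between groups was computed from peaks. Head-only and body-only counts were compared with the other splits of the 8 tagged libraries into 4 and 4. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. The merging of peaks and the assignment of regions to classes, without mock removal, were tested on simulated lists of the real lengths with 200 planted regions of each class. They recovered 100.0% of regions planted in all 8 lists, 96.5% of head-only regions and 81.0% of body-only regions, and called 0 elsewhere. Each planted region had a peak in every list of its class, and the other peaks were placed at random. Lost peaks, shared background and mock removal are thus not covered by these shares.

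The groups, comparisons, tests, overlap rules, most alternatives and the rule for named regions were fixed before the data were examined. The rule takes the 10 head-only, 10 body-only and 10 shared regions with the best mean rank over the libraries that hold them, and the 5 best regions found in both mock lists of a tissue. It also asks for every core clock gene and for members of other gene lists, and this part could not be applied. The annotation at hand is for Release 6 of the genome and the peaks are in dm3, so no region was assigned to a gene and regions are named by their dm3 coordinates. No genome sequence was at hand, so the planned motif shares were not computed. The alternatives covered the score threshold, the list length, the overlap rule, the chromosomes used, the mock removal, the replicate block and leaving out each replicate number. Leaving out each pull-down library from the peak-number tests, leaving out head mock replicate 1, shortening all 8 tagged lists to the same length, using only the best 10% of each mock list and ranking by the second score were added after the data were seen.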

Results

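The data are 12 lists of ChIP-seq peaks for CLK and CYC, the pair of transcription factors that drive the circadian clock and act together on E-box elements. Peaks were called in V5 pull-downs from fly heads and bodies at ZT13, for tagged CLK, tagged CYC and untagged mock flies, with 2 replicates of each. The lists hold 58157 peaks in all, from 73 in a body mock library to 13729 in a head CLK library. The comparisons address which sites the pair occupies above the background of the antibody, whether CLK and CYC share them, and which sites are specific to heads or to bodies. Positions are in dm3, the build of the lists. Depth per library is unknown, so a missing peak means that none was called and not that a site was unbound.

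Tagged pull-downs from bodies gave far more peaks than mock pull-downs from bodies, and in heads the gap depended on the mock library. Body CLK gave 1793 ± 905.1 peaks (mean ± SD, n = 2) and body CYC 2622 ± 1903, against 124 ± 72.12 in body mock. Head CLK gave 9169 ± 6449 peaks and head CYC 8467 ± 5118, against 6904 ± 7323 in head mock. Head mock replicate 1 alone held 12082 peaks, more than either replicate 2 list of the tagged heads, and head mock replicate 2 held 1726. The leading mock peaks of both tissues lay on the heterochromatic scaffold XHet. The best region found in both head mock lists was XHet 194280 to 194589, with first scores of 85.8 and 78.9, and the best in both body mock lists was XHet 191121 to 191388, with 50.7 and 69.7. XHet peaks filled 9 to 12 of the 20 best places in each of the 4 mock lists, and at most 1 of the 20 best places in each tagged list. Tagged libraries exceeded mock libraries by 2.43 on the log2 scale, or 5.39-fold (exact permutation test within tissue, two-sided p = 0.01333, n = 8 and 4). The difference was 17.0-fold in bodies, where 4 of 4 tagged libraries exceeded both mocks, and 1.71-fold in heads, where 2 of 4 did. Within heads it was 4.52-fold (log2 2.18) without mock replicate 1 and turned to a log2 difference of -0.63 without mock replicate 2. That last value sets tagged lists of both replicate numbers against mock replicate 1. Among replicate 1 lists, head CLK and CYC held 13729 and 12086 peaks against 12082 in mock. Among replicate 2 lists they held 4609 and 4848 against 1726. Within bodies the log2 difference was 3.46 without mock replicate 1 and 4.71 without mock replicate 2. Over both tissues the log2 difference without head mock replicate 2 was 1.73 and the exact permutation p was 0.08.

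**Figure D1:**
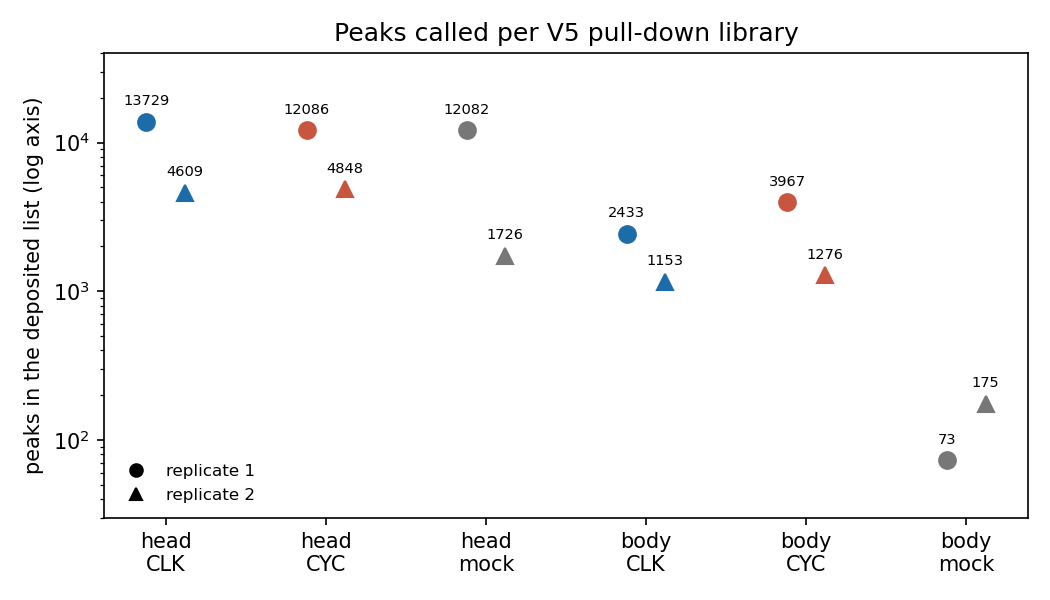
Number of peaks in each deposited list (log axis), by tissue and factor, with a circle for replicate 1 and a triangle for replicate 2. Body mock lists hold 73 and 175 peaks and body tagged lists 1153 to 3967, whereas head mock replicate 1, with 12082, lies among the tagged head lists.

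The mock peaks covered much of what the head pull-downs found and little of what the body pull-downs found. Of 3928 reproducible head CLK peaks, 46.3% (95% interval 44.7 to 47.9) overlapped a head mock peak, and of 2524 reproducible head CYC peaks, 61.7% (59.8 to 63.6) did. In bodies 8 of 600 reproducible CLK peaks (1.33%, 0.577 to 2.61) and 8 of 776 reproducible CYC peaks (1.03%, 0.446 to 2.02) overlapped a body mock peak. The overlap exceeded shifted placements 8.38-fold for head CLK, 8.77-fold for head CYC, 12.3-fold for body CLK and 12.1-fold for body CYC. The mock lists themselves differed in length, with 12082 and 1726 peaks in heads and 73 and 175 in bodies. The folds are therefore not comparable between tissues. The head values rest on mock replicate 1, since mock replicate 2 alone overlapped 5.45% of the CLK peaks and 8.64% of the CYC peaks. Of the 500 best peaks of head mock replicate 1, 87.2% were in both CLK and CYC replicate 1 heads and 10.6% in both replicate 2 heads. Above the median score the head CLK share was 26.5%, but the mock lists were cut at the same score. Whole mock lists overlapped 79% and 75% of the 100 best peaks of head CLK replicates 1 and 2. Of all peaks of these 2 lists they overlapped 54.0% and 42.1%. The difference between tissues in the shares with mock was not tested.

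In each tagged group the replicates shared 19.6% to 28.6% of the longer list and a larger part of the shorter list. The head CLK lists had 3928 reproducible peaks, which is 28.6% of the 13729 peaks of replicate 1, and 81.9% of the shorter list (80.8 to 83.0) overlapped the longer list. At equal length 2608 of 4609 head CLK peaks and 1391 of 4609 head CYC peaks were reproducible. The share of the shorter list was 49.2% in head CYC (47.7 to 50.6), 49.4% in body CLK (46.4 to 52.3) and 56.6% in body CYC (53.8 to 59.3). In head mock 587 of the 1726 peaks of the shorter list overlapped the longer list, with 625 reproducible peaks, and in body mock 7 of 73 peaks were reproducible, none of them on the main chromosome arms. Reproducible peaks exceeded shifted placements 13.1-fold in head CLK, 8.18-fold in head CYC, 47.0-fold in body CLK, 35.2-fold in body CYC, 5.16-fold in head mock and 24.6-fold in body mock. The body mock value rests on 7 peaks, a number that the highest of the shifted placements also reached. Longer lists overlap more when shifted, with a mean of 299.2 peaks in head CLK and 12.8 in body CLK. The folds are therefore not comparable between tissues. The best peaks by the first score were shared most often, a pattern favoured by choosing that score after its highest peaks were seen to coincide. Of the 100 best peaks, 86% to 100% overlapped the other replicate in the 8 tagged lists. Above the median score, reproducible peaks numbered 962 in head CYC and 147 in head mock.

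Ranked by the first score, the best peaks of CLK and of CYC nearly all overlapped a peak of the other factor in the same tissue. This overlap fell off among weaker peaks. The choice of that score, made after its highest peaks were seen to coincide in the tagged lists, favours this pattern. These shares are given for the first score only. Of the 100 best peaks of each tagged list, 97% to 100% overlapped a peak, of any rank and either replicate, of the other factor in the same tissue. Of the same 100 best peaks, 71% to 82% in heads and 1% to 6% in bodies also overlapped a mock peak of their tissue. Over whole lists the share with the other factor was 41.3% to 67.9%. At the 173 regions with a peak in all 8 tagged lists, CLK and CYC midpoints of the same tissue and replicate number lay a median of 13 to 24 bp apart. Midpoints of head and body lay a median of 24 bp apart for CLK and 14 bp apart for CYC in replicate 1. Among reproducible peaks without a mock peak, 578 of 2110 head CLK peaks (27.4%, 25.5 to 29.3) overlapped a head CYC peak, 67.9-fold above shifted placements. In bodies 300 of 592 CLK peaks (50.7%, 46.6 to 54.8) overlapped a CYC peak, 172-fold above shifted placements. Shifted placements gave a mean of 8.51 overlaps in heads and 1.74 in bodies, so these folds are not comparable between tissues. Counted from CYC, 578 of 966 head peaks (59.8%, 56.7 to 62.9) and 298 of 768 body peaks (38.8%, 35.3 to 42.3) overlapped a CLK peak. Heads held 771 regions with peaks in both CLK libraries and neither CYC library and 139 of the opposite kind, whereas bodies held 62 and 174. These differences were not tested across libraries, and with the replicate 2 lists alone 33.5% of body CLK peaks overlapped a CYC peak. The number of peaks did not differ detectably between the factors (log2 difference, CLK minus CYC, -0.19, exact permutation p = 0.7222, n = 4 and 4), and the smallest p that 36 arrangements allow is 0.05556. The sign of this difference was positive (0.35) when only peaks above the median score were counted, and 0.08 to 0.22 without body CLK replicate 2, body CYC replicate 1, head CLK replicate 2 or head CYC replicate 1.

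**Figure D2:**
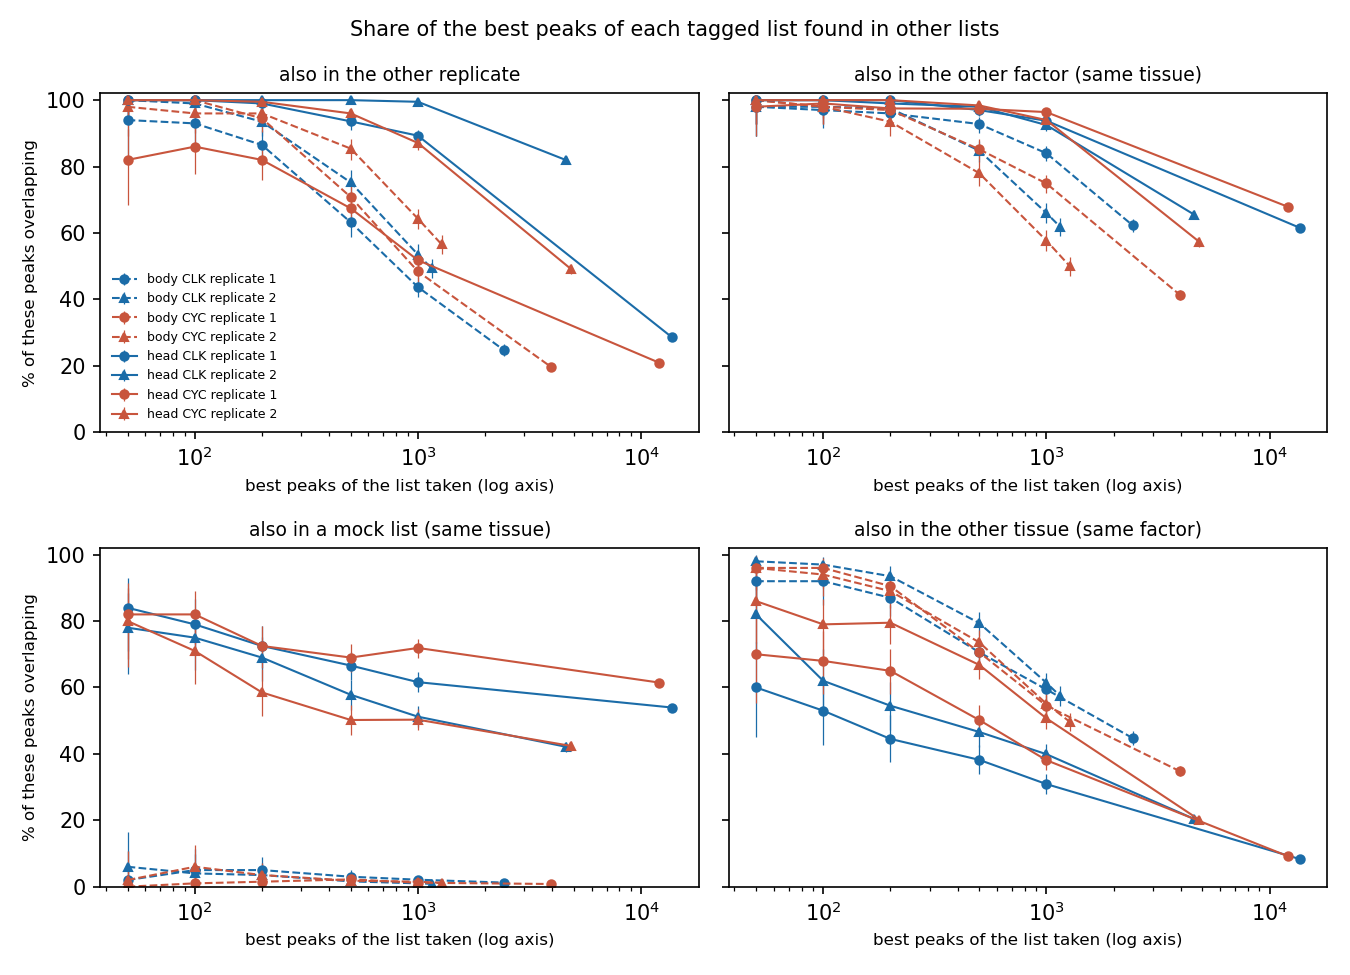
Share of the best peaks of each tagged list (vertical axes, percent, with Clopper-Pearson 95% intervals) that overlap a peak of another list, against the number of best peaks taken (log axis). Solid lines are heads and dashed lines are bodies, blue is CLK and red is CYC, and circles and triangles are replicates 1 and 2; among the 100 best peaks 71% to 82% of head peaks and 1% to 6% of body peaks overlap a mock peak of their tissue.

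By the first score, the strongest peaks lay at the same few places in heads and bodies. That score was taken after it was seen to be highest at the same positions in the tagged lists. The agreement of the best ranks is therefore not independent of the choice of score. The best mean ranks over the 8 tagged lists belonged to 3L 7828200 to 7828522, 3L 7826767 to 7827090, 2L 3507238 to 3507569, 2L 5303180 to 5303504 and 2L 5305472 to 5305811, which took ranks 1 to 6 in every tagged list. The first score of 3L 7828200 to 7828522 was 820.2 and 635.0 in body CLK, 1622 and 1114 in body CYC, 1393 and 613.6 in head CLK and 819.1 and 611.9 in head CYC. The next 5 were X 2578927 to 2579251, 2L 5301020 to 5301636, 2L 5303791 to 5304128, 2L 5302660 to 5303004 and 3R 21954117 to 21954439. These 10 regions fall outside the rule for named regions and were chosen after their values were seen, because head mock replicate 1 has a peak at each of them. That peak ranked from 114 to 1555 among the 12082 peaks of the mock list, with first scores of 7.02 to 17.2. None of the other 3 mock lists has a peak at them.

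After removal of regions with a mock peak, heads had 540 regions, bodies had 299 and 93 were shared. The shared regions made up 31.1% of the body regions (25.9 to 36.7), 77.8-fold above shifted placements. The best shared region was 3R 278185 to 278528, at ranks 15, 13, 7 and 7 in body CLK and CYC and 52, 27, 14 and 10 in head CLK and CYC. It was followed by 2L 12003058 to 12003583, 2L 6612311 to 6612633, 2L 478747 to 479076, 3R 628872 to 629210, 3R 20394205 to 20394553, X 2579385 to 2579717, X 2579861 to 2580183, 3R 6217668 to 6217998 and X 9477993 to 9478344. Mock removal took 787 of 1327 head regions (59.3%) and 4 of 303 body regions. Without it 173 of the 303 body regions were head regions (57.1%, 51.3 to 62.7), and without head mock replicate 1 alone the share was 51.5%. With single replicates the share was 19.0% from the replicate 1 lists and 51.5% from the replicate 2 lists. Tagged head libraries had 4.02-fold more peaks than tagged body libraries, 4.75-fold for CLK and 3.40-fold for CYC (exact permutation p = 0.05556, the smallest that 36 arrangements allow, n = 4 and 4). Above the median score the difference was 2.28-fold (exact permutation p = 0.1667).

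**Figure D3:**
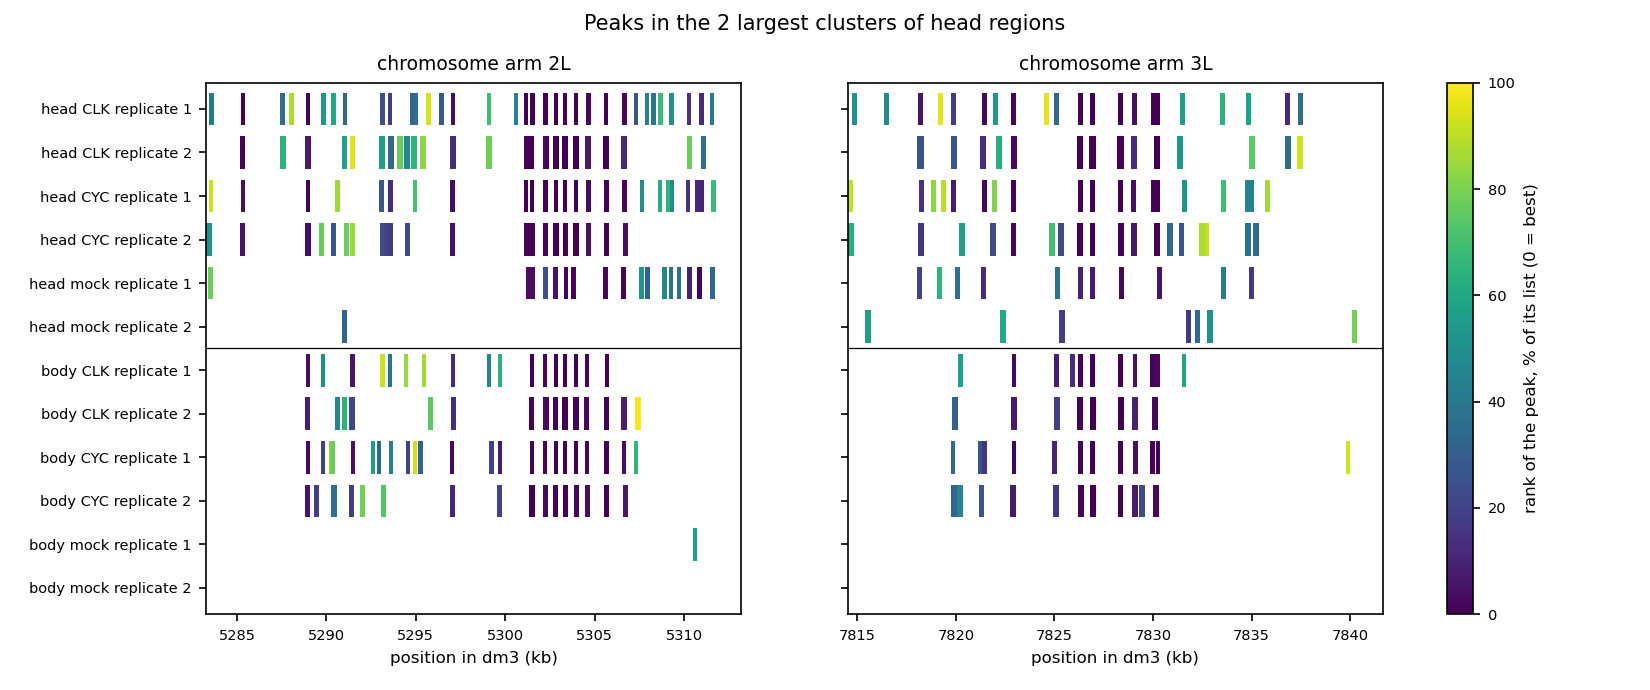
Peaks of all 12 lists in the 2 largest clusters of head regions, by position on arms 2L and 3L (kb, dm3), with a line for each library. Colour gives the rank of the peak in percent of its list, with 0 the best; the tagged lists share their best peaks, and of the mock lists head mock replicate 1 has peaks at most of these places.

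Heads had 273 regions with a called peak in all 4 tagged head libraries, in no tagged body library and in no mock list. The best was X 11677107 to 11677435, at ranks 27 and 29 in head CLK and 32 and 56 in head CYC, with first scores of 279.1 and 108.6 in CLK and 78.2 and 34.9 in CYC. A pair of neighbours on 2L came next, 14249981 to 14250303 at ranks 46 to 77 and 14249343 to 14249687 at ranks 63 to 112. They were followed by 3R 20369070 to 20369396, X 8018149 to 8018483, 2L 21311001 to 21311348, 2L 9704501 to 9704880, 3R 22268649 to 22268971, 3L 21442202 to 21442580 and 2L 5285151 to 5285474. The last of these ranked 35 and 64 in head CLK and 435 and 272 in head CYC. The median rank of head-only regions lay at 14.7% to 26.7% of the list, with 0 the best, and 4 to 6 of them were among the 100 best peaks of each head list. A further 173 head regions without a head mock peak had a peak in 1 to 3 body libraries. The count was 801 without mock removal and 709 without head mock replicate 1. It was 1581 from the replicate 1 lists alone, 1120 from the replicate 2 lists alone and 117 among peaks above the median of the second score.

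Bodies had 33 such regions. The best was 3L 8675426 to 8675744, at ranks 38 and 40 in body CLK and 33 and 37 in body CYC, with first scores of 59.6 and 34.3 in CLK and 87.5 and 51.0 in CYC. It was followed by X 9094157 to 9094470, 3R 7581687 to 7582006, 2L 3312533 to 3312841, 3R 11830702 to 11831308, 2L 21082585 to 21082922, 2R 20846735 to 20847056, 3L 4115837 to 4116230, 3L 8692782 to 8693171 and 2R 10113193 to 10113511. The fourth of the body-only regions, 2L 3312533 to 3312841, ranked 32 and 21 in body CYC and 75 and 675 in body CLK. A further 94 body regions without a body mock peak had a peak in 1 to 3 head libraries. Of the 100 best peaks of each body list 92% to 97% overlapped a head peak of the same factor. Of the 100 best peaks of each head list 53% to 79% overlapped a body peak. The head lists searched (4609 to 13729 peaks) were longer than the body lists (1153 to 3967), and these shares were not compared at equal length. Head-only regions outnumbered body-only regions 8.27-fold, but the head lists were longer. With all 8 tagged lists shortened to their 1153 best peaks the counts were 53 head-only and 58 body-only regions, or 172 and 64 without mock removal. Body-only regions numbered 619 from the replicate 1 lists alone, 69 from the replicate 2 lists alone and 14 among peaks above the median of the second score.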

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

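The test of the difference between tissues and the tests without single libraries were chosen after peak numbers had been seen; the tests of replicate 2 and of equal list length were added after the first test of replicate 1 had been seen, and the other tests in this part were set beforehand. The tagged-minus-mock difference in peak number was larger in bodies than in heads by 3.32 on the log2 scale, or 9.96-fold (approximate permutation of residuals from the additive model, p = 0.03111). This tissue difference in the effect of the tag is what marked the result. It rests on several libraries. Without head mock replicate 1 it was 1.91, or 3.77-fold (permutation p = 0.12), and without head mock replicate 2 it was 4.72 (permutation p = 0.01333). The permutation p also passed 0.05 without body CLK replicate 1 (0.05333), body CYC replicate 1 (0.05333), body mock replicate 1 (0.08), head CLK replicate 2 (0.06) or head CYC replicate 2 (0.06). Labels were not permuted within replicate number, although lists of the same number are alike. Replicate 1 lists held 2433 and 3967 tagged against 73 mock peaks in bodies, and 13729 and 12086 against 12082 in heads. Replicate 2 lists held 1153 and 1276 against 175 in bodies, and 4609 and 4848 against 1726 in heads.

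Head mock replicate 1 came from flies without a tag, yet it has peaks at each of the 10 strongest tagged regions and at most head regions. Of its 500 best peaks 87.2% (83.9 to 90.0) were in both CLK and CYC replicate 1 heads, which met the 50% set beforehand in favour of a background pulled down in every head library, but the test added later for replicate 2 found 10.6% (8.04 to 13.6) in both replicate 2 heads, under the 20% set to exclude it, which argues against such a background in replicate 2. Something shared by the replicate 1 head libraries, such as a batch, may be the source of these 500 peaks. With the 4 tagged head lists at equal length, 90.0% and 89.2% of them were in CLK and CYC replicate 1. In CLK and CYC replicate 2, 20.6% and 18.4% were found. The 500 best peaks of mock replicate 2 showed no such preference for replicate 2 (18.6% and 29.4% in replicate 1, 18.4% and 22.8% in replicate 2). At the 10 strongest tagged regions the peaks of mock replicate 1 ranked 114 to 1555, so not all are among its 500 best. Those regions also lead the replicate 2 and body lists. The tests on the 500 best peaks thus do not decide why mock replicate 1 has peaks there. Signal carried over from tagged libraries, which could itself be shared by number, stays open. Across 760 head regions the mock rank followed the tagged rank with a Spearman rho of 0.27 (bootstrap interval 0.205 to 0.335). This rho lies between the 0.1 set to exclude carry-over and the 0.3 set for it. Mock peaks were present at 68.4% of the best 10% of head regions and 59.9% of those ranked below the median (difference 8.48 points, -0.254 to 17.2). Between these tiers mock peaks were less frequent than in either, so their share did not fall steadily with rank. The labels name no batch, no biological explanation was tested for a difference between replicates, and regions are not independent replicates.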

How the results depend on the processing

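Head against body peak number kept its direction under all 13 alternatives (log2 difference 1.19 to 2.41), with the lowest value among peaks above the median score. Tagged against mock kept its direction under all 17 (1.73 to 3.13) and its call under 14. It lost the call without replicate 1 or without replicate 2 of every group (2.12 and 2.74, exact permutation p = 0.1111, where 9 arrangements give no smaller p) and without head mock replicate 2 (1.73, p = 0.08). Over all leave-outs it ranged from 1.73 to 3.13. Within heads alone, a comparison added after the data were seen and not tested, the log2 difference of 0.77 ranged from -0.63 without head mock replicate 2 to 2.18 without head mock replicate 1. Within bodies alone it ranged from 3.46 to 4.71. CLK against CYC turned positive among peaks above the median score (0.35) and without body CLK replicate 2, body CYC replicate 1, head CLK replicate 2 or head CYC replicate 1, with leave-outs from -0.59 to 0.22. The labels give replicates a number only, yet lists of the same number are alike. Replicate 2 peaks are wider in 6 of 6 groups, and replicate 1 lists are longer in 5 of 6. Measured as fold over shifted placements and not as plain shares, 13 of 16 overlaps between groups are larger with the same number. Pairs of CLK and CYC lists enter these 16 from both sides, and overlaps with body mock rest on few peaks. Every overlap that goes the other way is in bodies. With the replicate number as a replicate block, tagged against mock was 2.43 (exact permutation p = 0.01235) and CLK against CYC -0.19 (exact permutation p = 0.5). Head against body kept its value (exact permutation p = 0.125, the smallest that 16 arrangements allow). Depth is unknown, so list length stands in for it here. Unless a clause says otherwise, the cause of a change was not tested.

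Among peaks above the median score, reproducible peaks numbered 962 in head CYC and 147 in head mock. With the mock lists cut at the same score, the share with a mock peak was 26.5% in head CLK and 41.7% in head CYC. CLK-CYC sharing in heads was then 23.1% and head-body sharing 38.3%. With tagged lists shortened to the shortest of their tissue, reproducible peaks numbered 2608 in head CLK, 1391 in head CYC and 510 in body CYC. The share with mock was then 49.9% in head CLK, and head-only regions numbered 173. With an overlap of at least 50%, head mock had 392 reproducible peaks and the shares with mock were 38.7% (CLK) and 50.1% (CYC). With midpoints within 100 bp these were 301, 34.6% and 45.2%. On the main arms alone body mock had 0 reproducible peaks, which follows from their place on scaffolds. Without mock removal, by construction, more head regions stayed: CLK-CYC sharing in heads was 34.2%, head-body sharing 57.1% and head-only regions 801.

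When a replicate number was left out, and head mock replicate 1 in turn, values ranged widely. For the tagged groups, a single library stood for its group only when a replicate number was left out. Among the values that follow, 5.45%, 33.1% and 709 came from leaving out head mock replicate 1 alone. The share with mock ranged from 5.45% to 52.8% in head CLK, from 7.82% to 60.0% in head CYC, from 0.534% to 0.867% in body CLK and from 0.202% to 0.940% in body CYC. CLK-CYC sharing ranged from 33.1% to 36.3% in heads and from 33.5% to 58.7% in bodies, and head-body sharing from 19.0% to 51.5%. Head-only regions ranged from 709 to 1581 and body-only regions from 33 to 619.

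The remaining alternatives were chosen after the data were seen. With all 8 tagged lists at the length of the shortest, head-body sharing was 22.2%, with 53 head-only and 58 body-only regions. With no mock removal as well, these were 46.6%, 172 and 64. With the best 10% of each mock list as mock, CLK-CYC sharing in heads was 32.9%, head-body sharing 46.7% and head-only regions 720. Above the median of the second score, head-body sharing was 50.5%, with 117 head-only and 14 body-only regions. With lists shortened by the second score to the shortest of their tissue it was 18.7%, with 137 head-only and 29 body-only regions, and with all 8 at the length of the shortest 1.60%, with 25 and 72. The planned E-box, GATA and gene-list results and their alternatives were not run, because no sequence or annotation of the build of the lists was at hand.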

Other observations

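The tests of the splits of the 8 libraries and of weak peaks in the mock lists were chosen after the results were seen. The comparison at equal list length was added after the counts of head-only and body-only regions had been seen, and its bound was written before its own result. Head and body regions were grouped along the chromosomes. With mock peaks ignored, the 1327 head regions formed 995 clusters, of which 788 held a single region, where random placement gave a mean of 1249. The largest held 12 regions on 2L from 5285151 to 5306877 and 11 on 3L from 7818052 to 7835365. Random placement gave at most 6 regions in a cluster. The 303 body regions formed 223 clusters, of which 185 held a single region, where random placement gave a mean of 298.8. The largest body clusters held 8 regions each and lay at the same places, on 2L from 5296892 to 5305811 and on 3L from 7819742 to 7830372, against at most 4 with random placement. Of the regions in the head clusters, 9 on 2L and 7 on 3L were present in all 8 tagged lists. Head clusters that followed were on 3R from 21943081 to 21954439 (8 regions), 2R from 14688441 to 14697956 (7 regions), 2L from 3504676 to 3509081 (6 regions) and 3L from 8685549 to 8698768 (6 regions).

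The 10 strongest regions lay on 2L, 3L, X and 3R. The core clock genes tim and vri are on 2L, Clk, Pdp1 and cyc on 3L, per on X, and cry and cwo on 3R. An arm assigns no gene, and the positions of these genes in dm3 were not used here. X makes up 18.8% of the main-arm length. It held 35 of 299 body regions (11.7%, 8.29 to 15.9) and 191 of 1327 head regions with mock peaks ignored (14.4%, 12.6 to 16.4), both below its share of length. Of the head regions without a mock peak, X held 91 of 540 (16.9%, 13.8 to 20.3).

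The split of the tagged libraries by tissue parted more regions than any other split, but list length follows the same split. Head tagged lists held 4609 to 13729 peaks and body tagged lists 1153 to 3967. The splits therefore cannot separate tissue from list length, and no conclusion on a chance assignment of libraries is drawn from them. Of the 35 splits of the 8 tagged libraries into 4 and 4, only the real split (1 split) gave as many as 273 head-only regions, and the highest of the others gave 30. For body-only regions, the smaller direction of the real split, again only that split (1 split) reached 33. The highest of the others gave 4 in its smaller direction and 30 in its larger, so the margin is narrow if every direction is counted. The excess of head-only over body-only regions is a separate matter. Longer head peak lists may account for it, since with all 8 lists shortened to 1153 peaks head-only regions were 47.7% of both kinds together (38.2 to 57.4), under the bound of 60% set for it. Ranked by the second score, equal lists gave 25 head-only and 72 body-only regions. These counts include the removal of mock peaks, which takes far more regions in heads. Without it head-only regions still outnumbered body-only regions 2.69-fold at equal length by the first score (172 and 64). Whether list length accounts for the excess thus depends on mock removal. A true difference between the tissues was not tested apart from list length, and the rounds of sonication follow the tissue and cannot be separated from it in this design.

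Chromosome 4 held 3.68% and 1.39% of head CLK peaks, 8.18% and 3.78% of head CYC peaks and 7.57% and 6.20% of head mock peaks, where its share of the covered length is 1.03%. In bodies it held 19.2% of the 73 peaks of mock replicate 1 (10.9 to 30.1), 1.14% of mock replicate 2 and 0.173% to 0.627% of the tagged lists. Background of the V5 pull-down could place peaks there, but the test does not decide: 0 of 540 head regions without a mock peak lay on chromosome 4, and the removal of mock peaks by itself favours that outcome. The share in head CYC replicate 1 also exceeded that of mock replicate 1. Weak peaks in long lists are argued against for head mock replicate 1, whose 1000 best of 12082 peaks had 6.5% on chromosome 4. For head mock replicate 2 the test cannot decide. Its 1000 best peaks, with 7.4% there, are most of its 1726. For the tagged lists the explanation by weak peaks stays open, since the 1000 best peaks had 0.6% and 0.5% there in head CLK and 3.4% and 0.8% in head CYC. No biological explanation was tested for this pattern.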
